A study of Arabidopsis thaliana with 116 samples.

How the data were processed

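RNA from developing seeds of 116 recombinant inbred lines of Arabidopsis thaliana was hybridised as biotin-labelled target to 1 Affymetrix array per line. Plants were grown with 16 h of light at 20 °C and 8 h of dark at 16 °C after 3 days of stratification, siliques of 6 plants were pooled per line, and RNA was taken from 200 mg of their seeds, per the labels. The deposited values are log2 probe set signals made by the authors with RMA, per the submitters' processing notes; the version of RMA, the genome build and any batch or scan date are not given in the sources used here. RMA subtracts background, sets the arrays to a common distribution and summarises the probes of a set, so differences in overall RNA amount between lines are removed and the levels of dim probe sets are compressed. Only probe set values were held here, so probe-level ratios, on which the study's own markers rest, were not analysed here, and neither were arrays of the parents. The table held 22810 probe sets; 64 array controls were left out of the tests.

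Names came from the probe annotation held here, joined to a RefSeq gene table of assembly TAIR10.1. Of 22746 probe sets, 13513 had 1 gene, 503 had several genes and 8730 were unnamed; 13436 of the 1-gene probe sets matched a gene of the table by Entrez ID and 77 did not. Matched probe sets were 13367 nuclear and 69 plastid; 18 of those not matched carried the symbol of a mitochondrial gene of the table. The table served for names and for the order of 37887 nuclear genes; no coordinates were used. Probe sets with several genes or no gene were counted and not named.

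Lines were grouped by the first letter of their names. Q and R lines were compared with limma 3.58.1 in R 4.3.3 (lmFit, eBayes), with Benjamini-Hochberg adjustment over all tested probe sets and a threshold of 0.05. Gene lists were tested with limma camera (preset correlation 0.01), with an estimated correlation and with fry beside it, using for each gene the probe set with the highest mean. The comparison was repeated for 100 splits of the lines into groups of the same sizes, the real split among them. Bimodal probe sets were found with a mixture of 2 normal components of equal SD, requiring modes at least 4 SD and 1 log2 apart, a smaller component of at least 0.2 and a gain in BIC of at least 10. Lines with a posterior between 0.1 and 0.9 were left out of recombinant counts. Upper modes of a pair can fall in the same or in opposite lines, so the smaller of the matching and non-matching shares was taken as recombinant. Segregation was tested against 1:1 with two-sided exact binomial tests and between letters with Fisher's exact test. Families were to be found by description words, which the gene table lacks, so names and synonyms were searched instead and 2 of 8 families had enough genes to test.

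For the association scan, bimodal nuclear genes were gathered in bins of 200 consecutive annotated genes. The score of a bin was the mean posterior of its genes, aligned to the gene with the most separated modes, and was used as a continuous covariate with the population letter; a gene was never scored against itself, and no mode was assigned to a parent. Each probe set took the bin with the largest moderated t, its p came from the pooled null of 100 permutations of lines within letters, and Benjamini-Hochberg adjustment followed. An association was local when the peak lay on the gene's chromosome within 3 bins. Permuted counts were taken at the t of the weakest call in the data, 3.66; this replaced a count at each permutation's own threshold after that count had been seen. Interactions with the letter were fitted in limma for the associated probe sets, without bimodal genes that were associated locally. Coherence of a list was the mean pairwise correlation of its members against 10000 random lists of matched signal, and correlations between list scores used 100000 permutations, two-sided, adjusted over 45 pairs. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used for these steps, and matplotlib 3.10.9 for the plots.

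The comparisons, gene lists, most alternatives and the rule for named genes were fixed before the data were examined. The rule named, between letters, the 12 smallest p in each direction and every called organelle gene; the 15 bimodal genes with modes farthest apart and any list member among bimodal genes; the 10 strongest local genes; the 6 strongest targets of the 3 bins with most distant targets; list members with a distant bin; the 5 smallest interaction p; for each list the 3 highest and 2 most variable members; and the 10 most variable genes that were not bimodal. Other genes named were chosen after their values were seen. Alternatives were a filter at a mean of 5 log2, other normalisations, covariates for hidden structure and RNA quality, array weights, removal of probe sets with shared names, other mixture thresholds, other bin sizes and windows, and removal of principal components. An organelle score, the standardised mean of the plastid genes that were bimodal within both letters, was added after the data were seen, and probe sets with an adjusted p under 0.05 and a slope of at least 0.25 log2 per SD of the score were counted as rising. The count of permutations reaching each leading bin and the calls of list members with components removed were added then too.

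The limma comparison, the mixture, the scan, coherence and the slopes on the organelle score were checked on simulated data made from these arrays with 22746 probe sets. Recombinant shares, segregation, interactions, list correlations and list tests between letters were not checked in this way. The limma, mixture and coherence checks drew independent noise from the mean and SD of each probe set, so correlation between probe sets was absent. Their false calls therefore do not stand for those in real data, where other splits of the lines called up to 157 probe sets. The simulated modes had an SD of 0.2, against a median of 0.247 in bimodal nuclear genes. Between letters, limma recovered 92% of simulated shifts of 0.25 log2 and 98% of shifts of 0.5 log2, and called 7 unchanged probe sets. The mixture recovered 50% of probe sets with modes 1 log2 apart and 100% of those 2 log2 apart, and called 0 unimodal ones. The scan recovered 46% of associations with 15% of the variance and 99% of those with 30%, and called 5 unchanged probe sets. The coherence test gave a list with 20% shared variance an adjusted p of 0.001 and called 0 of the other lists. Slopes on the organelle score of 0.5 SD of a probe set were recovered in 97.5% of cases, with 5 others called.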

Results

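The samples were developing seeds of 116 recombinant inbred lines of Arabidopsis thaliana, derived from reciprocal crosses of the accessions Col-0 and C24. Recombinant inbred lines are largely homozygous mosaics of their parents, so a parental difference at a locus appears as a contrast between lines. Line names began with Q in 59 lines and with R in 57 lines, and the labels did not state which letter stood for which direction of the cross. Seeds were collected 10 to 11 days after flower opening from 8 siliques on each of 6 plants per line. Each line was measured on 1 Affymetrix array, so the p-values measure spread between these lines and carry no estimate of variation within a line. Deposited values were RMA-normalised log2 signals for 22810 probe sets, of which 22746 were tested and 64 were array controls. Array medians lay between 5.84 and 5.99, and the correlation between arrays had a median of 0.986 with a lowest value of 0.959. The number of arrays limits the precision of each value.

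Several genes that seeds use to store protein and oil had high signal. The oil body gene AT3G01570 averaged 13.81 ± 0.056 log2 (SD, n = 116 lines), and the oleosin gene OLEO3 averaged 13.25 ± 0.101. Among the storage protein genes, AT1G03890 averaged 13.43 ± 0.12, the vicilin-like gene PAP85 averaged 13.30 ± 0.101 and AT2G28490 averaged 13.12 ± 0.0779. Other members were lower, with the storage protein gene AT2G18540 at 5.42 ± 0.31 and the oil body gene AT2G25890 at 10.01 ± 0.326, and levels of different probe sets also depend on their probes. The late embryogenesis abundant gene LEA (AT2G21490) was at 12.10 ± 0.269. The endosperm gene AGL62 was at 3.24 ± 0.0899, and the endosperm gene IKU2 was at 4.35 ± 0.136. Of 238 genes fixed in 13 lists, 54 had a probe set that could be named here, so each list stands for a part of its pathway.

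Reciprocal crosses place the same nuclear parents in different cytoplasms, and the comparison of Q with R lines asks which transcripts followed the letter of the line. The clearest differences were in signals for genes of the plastid genome. If the letters stand for the direction of the cross, the plastid genomes may also differ in sequence under the probes. Probe set values do not separate such a difference from one in transcript level. Signal for clpP, which encodes a subunit of the plastid Clp protease, was 10.13 ± 0.326 log2 in Q lines and 11.34 ± 0.275 in R lines (SD, n = 59 and 57), a Q minus R difference of -1.21 (limma, adjusted p = 7.31e-39). The photosystem II genes psbF, psbJ, psbE and psbL, which have consecutive locus tags, were higher in Q lines, by 0.85, 0.85, 0.91 and 0.68 log2. Photosystem II genes did not differ as a class. Of the others psbM was higher by 0.14 and psbZ lower by -0.19, while psbA, psbB, psbC, psbD, psbH, psbI, psbK and psbT did not pass. Lower in Q lines were rps2 by -1.05, rpoB by -0.80, rps18 by -0.77 and rpl33 by -0.77, while rpl20 (0.35) and rpoC1 (0.26) did not pass. Of the 69 plastid probe sets 21 passed the threshold, 9 higher and 12 lower in Q lines.

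**Figure D1:**
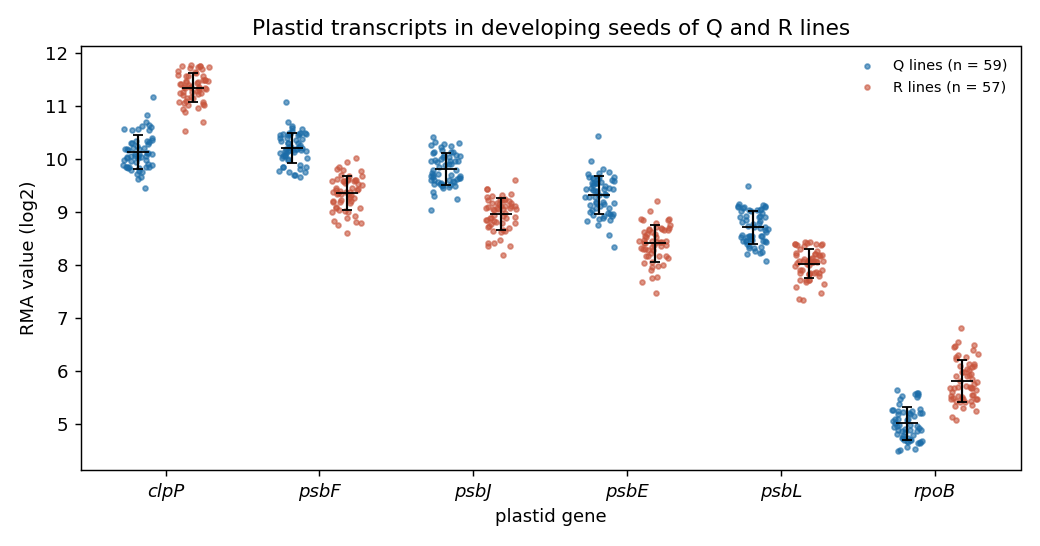
RMA log2 values of 6 plastid genes in Q lines (n = 59) and R lines (n = 57), with 1 point per line, black bars at the mean and whiskers of 1 SD. The clpP values run from 9.45 to 11.16 in Q lines and from 10.52 to 11.76 in R lines, and the 4 photosystem II genes shown are higher in Q lines.

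Smaller differences completed the plastid set. The cytochrome genes petA and petB differed in opposite directions, by 0.61 and -0.46 log2, and cemA differed by 0.46. The large Rubisco subunit gene rbcL was higher in Q lines by 0.27, accD by 0.37 (adjusted p = 0.0467) and psbM by 0.14. Lower in Q lines were ndhC (-0.28), ndhA (-0.23), ndhI (-0.17), rps4 (-0.23), rpoC2 (-0.21) and psbZ (-0.19). Over the 21 probe sets, 0 of 59 Q lines lay nearer to the mean of the R lines, and 0 of 57 R lines lay nearer to the mean of the Q lines; the probe sets had been chosen for differing between these lines. As a group, the 69 plastid genes had a median difference of 0.02, with 27 genes past the threshold adjusted over the list alone, 11 of them higher in Q lines. The fry test for change in either direction gave adjusted p = 2.5e-22, while camera, which tests for a common direction against other genes, gave p = 0.606. In the mitochondrial genome 1 of 18 probe sets passed, for nad1, at -0.21 (adjusted p = 0.0186), and the other probe sets for nad1 did not. Called differences for nad1, ndhI, psbZ, rps4, ndhA, rpoC2 and accD were lost with 10 principal components of the values as covariates, an alternative that left 15 plastid probe sets called.

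In the nuclear genome differences between Q and R lines were numerous and small. The largest statistics among genes higher in Q lines belonged to AT2G16750, at 6.94 ± 0.419 in Q and 6.49 ± 0.448 in R lines (SD, n = 59 and 57), a difference of 0.45 (limma, adjusted p = 0.000195). Others higher in Q lines were AT5G23750 by 0.40, AT3G26100 by 0.26, AT2G42040 by 0.26, AT3G49060 by 0.21 and AT4G33080 by 0.21. AT5G24870, AT4G24610, AT2G34200, TBL32, AT1G12810 and AT4G21323 were higher by 0.16 to 0.21. Lower in Q lines were AT5G40150, at 6.03 ± 0.238 against 6.27 ± 0.21 (difference -0.24, adjusted p = 8.92e-05), the RING finger gene RING1 (-0.30), the malate dehydrogenase gene MDH (-0.16), AT5G40030 (-0.16), AT2G01710 (-0.13), the trichome birefringence-like gene TBL25 (-0.13) and the peptide gene RALFL34 (-0.14). AT1G27210, AT3G04550, AT1G22730 and AT3G15690 were lower by sizes between -0.10 and -0.12, and AT2G07777 differed by -0.18. The probe set of AT2G07777 is not shown to be free of organelle signal, since 6 of 67 nuclear probe sets with AT2G07 tags rose with the plastid genes ndhF, petN and rps14. The nuclear probe sets past the threshold numbered 365, with 214 higher and 151 lower in Q lines, and their median absolute difference was 0.136 log2. Over all classes 698 probe sets passed, 416 higher and 282 lower in Q lines, of which 308 had no single gene name here. When each array's median was subtracted, 347 were higher and 417 lower, so the majority direction depended on the scaling. The count over all classes rose to 1368 with the 3' minus 5' difference of control probe sets, an RNA quality measure, as covariate. With 10 principal components of the values as covariates 12 nuclear probe sets passed, 4 of the 365 among them, and AT2G01710 was the only one of the 24 nuclear genes named above that kept its call.

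Of the fixed gene lists, none passed limma camera between Q and R lines, and 3 had an unadjusted p under the threshold. The 5 nuclear photosynthesis genes had a median difference of -0.11, with PORB, the light-dependent protochlorophyllide reductase, at -0.22 and the antenna gene LHCB4.1 at -0.11. The 4 seed coat genes had a median of -0.10, with AT3G50990 at -0.20 and the dihydroflavonol reductase gene DFR at -0.11. The 3 cell cycle genes had a median of -0.13, with the replication gene PRL at -0.21 and the Aurora kinase genes AUR1 at -0.13 and AUR2 at -0.07. Camera gave these lists adjusted p-values of 0.0806, 0.153 and 0.0806, and each had adjusted p = 0.624 with an estimated correlation. All 3 cell cycle genes passed adjusted over the list alone and 0 passed over all genes tested. The acyl carrier protein thioesterase gene FATB was higher in Q lines by 0.12 (adjusted p = 0.0386) and was the only nuclear member of a list past the threshold over all genes. Adjusted over their lists alone 1 fatty acid gene and 1 oil body gene passed, and 0 passed in the storage protein, late embryogenesis abundant, photosynthesis, seed coat, glucosinolate and mitochondrial lists. The oil body list had a median of -0.01 and a mean of 0.0088, so these differed in sign. The first principal component of all probe sets was also higher in Q lines, by 0.55 SD (permutation test, p = 0.00257). The 3' minus 5' difference of the control probe sets, a measure of RNA degradation, was 1.22 ± 0.355 in Q and 1.13 ± 0.365 in R lines (p = 0.174).

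The study read genotypes from hybridisation levels, and the matching question for probe set values is which genes split the lines into separate modes. AT4G29200 had a lower mode at 4.34 and an upper mode at 9.98 log2, a distance of at least 49.6-fold, with 70 of 116 lines in the upper mode. AT5G38180 had modes 4.58 apart, AT1G50290 4.29, AT1G23960 3.86, AT1G28590 3.71, AT4G20480 3.64, AT2G41650 3.56 and AT1G17860 3.50. Distances of AT4G14980, AT3G04200, AT3G19520, AT5G51490, AT2G14460, AT5G41250 and the carboxypeptidase-like gene scpl42 ran from 3.46 down to 2.71. The mixture model called 225 probe sets bimodal (0.989%), covering 124 nuclear genes with 30, 19, 22, 21 and 32 of them on chromosomes 1, 2, 3, 4 and 5. The lower mode was under 5 log2 in 42 of the genes (33.9%), where RMA compresses values and the distance is a lower bound, and no member of the fixed lists was bimodal. Probe set values do not separate a sequence difference under the probes from a difference in transcript level.

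**Figure D2:**
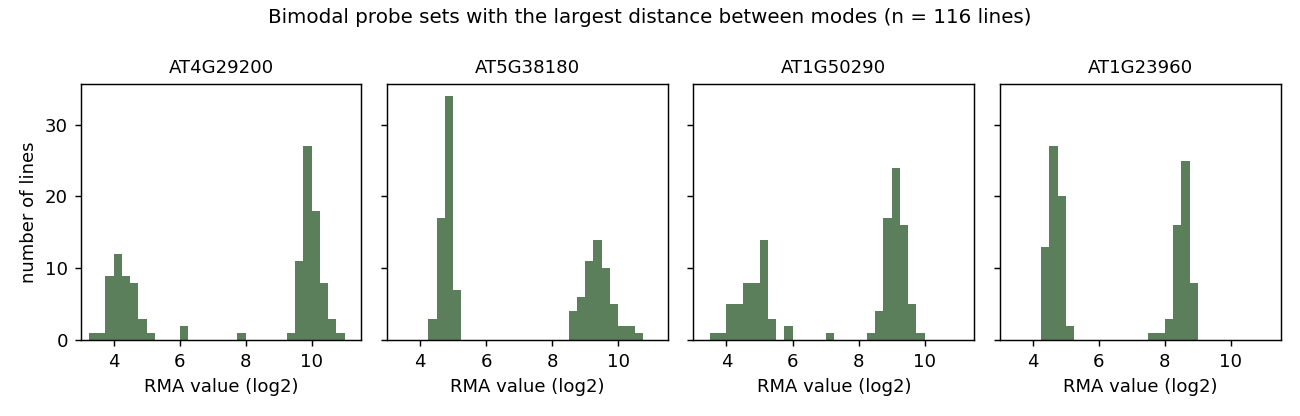
Number of lines (n = 116) by RMA log2 value, in bins of 0.25 log2, for the 4 genes with the largest distance between modes. AT4G29200 has 70 lines in its upper mode near 9.98 and the rest near 4.34.

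Bimodal plastid genes numbered 4. The upper mode of clpP held 2 of 59 Q lines and 55 of 57 R lines. The other plastid genes split each letter instead: the upper mode held 21 Q and 20 R lines for ndhF, 23 and 20 for petN, and 22 and 20 for rps14. Those genes split nearly the same lines, with 40 lines in the upper mode of all 3, 72 in the lower mode of all 3 and 4 lines mixed.

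Modes of neighbouring genes were inherited together, which bears on the linkage map the study set out to make. Pairs of bimodal genes 1 to 25 places apart in gene order had a median of 0.442% recombinant lines (10 pairs). The median was 5.22% at 101 to 200 places, 12.9% at 401 to 800 and 40.2% beyond 1600. Pairs on different chromosomes had a median of 46.7% (6083 pairs). The smaller of the matching and non-matching shares was counted, so pairs without linkage also fall short of an even split. Each of the 124 nuclear genes had its closest linkage on its own chromosome. AT1G50290, on chromosome 1, had no recombinant with the glutathione transferase gene GSTU26 in 115 lines although they lie 3642 places apart, and had 41.6% recombinants with AT1G49750, which lies 62 places away. Gene order came from the TAIR10.1 annotation, whose relation to the array design is not given in the sources used here.

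**Figure D3:**
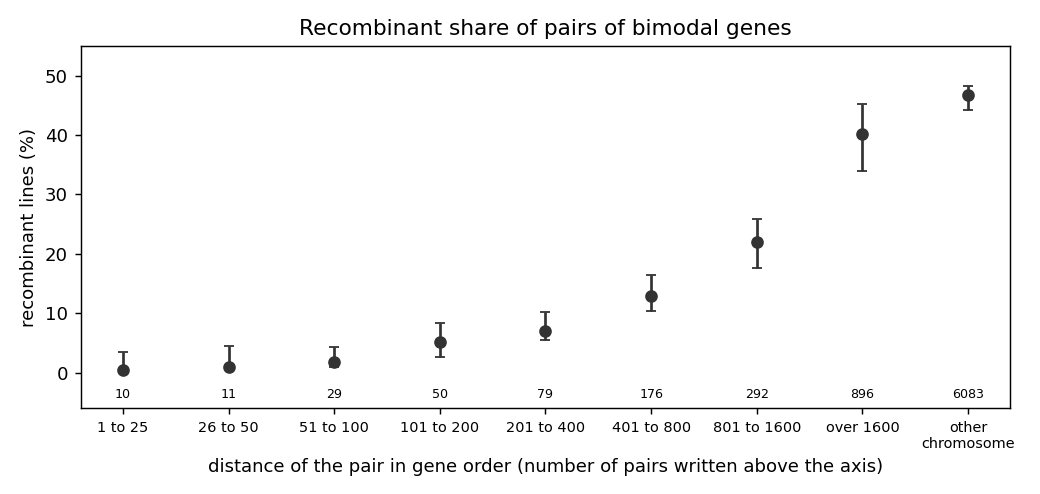
Median percent of recombinant lines for pairs of bimodal genes, against their distance in gene order, with whiskers from the lower to the upper quartile and the number of pairs above the axis. The smaller of the matching and non-matching shares is counted as recombinant. The median rises from 0.442% for the closest pairs to 46.7% for pairs on different chromosomes.

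Most bimodal genes segregated near 1:1, and 7 of 124 departed from it (two-sided exact binomial test, Benjamini-Hochberg; 18 at unadjusted p under 0.05). AT3G44630 and AT3G43510 on chromosome 3 had 70.7% and 66.4% of lines in the upper mode, with adjusted p of 0.0004 and 0.0132, and differed in 7.76% of lines. On chromosome 4, AT4G02540 had 35.3% (adjusted p = 0.0363), and its neighbour AT4G04180 had 37.1% in the matching mode. AT4G29700 had 24.3% where its neighbour AT4G29200 had 39.7% in the matching mode, with 15% recombinants at 66 places. AT1G52810 (28.4%), AT5G58980 (70.4%) and AT1G61500 (34.5%) also departed, where their nearest bimodal genes stood at 48.6%, 50.5% and 44.8%. With modes at least 5 SD apart, 2 genes departed. Upper mode shares did not differ between Q and R lines for any gene by Fisher's exact test after adjustment (0 of 124; 3 at unadjusted p under 0.05). Among gene families fixed beforehand, 0 of 24 cytochrome P450 genes and 1 of 45 UDP-glycosyltransferase genes were bimodal, and Fisher's exact test called neither (adjusted p of 1 and 0.692; 0 at unadjusted p under 0.05). Other families could not be tested with the names held here.

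The study's eQTL question, which loci move with the level of a transcript, was asked of a score for each of 91 chromosome bins built from the 124 bimodal genes. Signals of many genes followed a bin within 3 bins of their own. A sequence difference under the probes can give such a local association without a change in transcript level. Probe set values do not separate these, so the changes below are changes in signal. AT2G38180 changed by 0.84 ± 0.0298 log2 (SE, n = 116) from one end of the marker score to the other, and the score accounted for 87.4% of its variance. AT5G41710 changed by 0.98 (87.2%), AT3G18680 by 0.88 (86.2%), AT1G31910 by 0.89 (86.1%), AT4G13630 by 0.87 (85.9%) and AT5G56020 by 0.83 (85.9%). AT5G41950 (85.1%), AT4G16710 (84.7%) and AT5G50340 (84%) rose toward the upper mode of the lead marker, and AT1G11860 fell by 0.90 (84.9%). Local association was called for 2887 probe sets, which is 21.6% of the nuclear probe sets tested. Of these 2770 were not bimodal themselves, with a median of 28.7% of variance and a median absolute change of 0.24 log2. With a window of 1 bin 2225 were called as local, and with 10 principal components removed 1854. The highest local count in 100 permutations, at the same t, was 31. Signs give the direction toward the upper mode of the lead marker of the bin and assign no parent, and 4954 further associated probe sets had no position here.

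Distant associations, with a bin elsewhere in the genome, were called for 3079 probe sets, 2282 of them on another chromosome and 797 on the same one. AT1G50290 was kept at its annotated place and counts among them, with 97.1% of its variance at the bin of GSTU26. Its own bin averages it with AT1G49750, to which it showed little linkage, so that score stands for no single locus. The bin of AT4G02540, near the start of chromosome 4, had 467 targets, 254 of them lower toward its upper mode, and 402 lay on other chromosomes. Its strongest targets were the vacuolar processing enzyme gene GAMMA-VPE (-0.42 ± 0.0392 log2, SE, n = 116; 50.9% of variance), AT5G19120 (1.43; 50%), AT4G37180 (0.97), AT1G17830 (0.74), AT1G55760 (-0.52) and AT1G68670 (0.69). The bin of UGT85A7 on chromosome 1 had 263 targets, 195 of them on other chromosomes, led by AT3G07600 (-0.49; 44.5%), AT1G14270 (-0.31), AT3G13175 (-0.46), AT1G32470 (-0.36), AT3G11560 (-0.17) and AT1G29250 (-0.29). Of these, AT1G14270, AT1G32470 and AT1G29250 also lie on chromosome 1, so linkage to loci near the genes themselves is not excluded. The bin of AT4G04180 had 159, with 130 on other chromosomes, led by AT4G08280 (-0.86; 77.5%), AT4G08110 (-0.41), EXO (-1.03), AT1G79970 (-0.26), AT4G08240 (-0.19) and AT2G33255 (-0.21); AT4G08280, AT4G08110, EXO and AT4G08240 lie in the stretch without markers that follows AT4G04180, and count as distant only because of the 3-bin window. With a window of 6 bins the distant count was 2781. In 100 permutations at the same t the highest distant count was 665 in all, and the highest count of targets on other chromosomes in a single bin was 137. A bin with as many distant targets arose in 0 of the 100 permutations for AT4G02540 and UGT85A7 and in 1 for AT4G04180, whose 130 targets on other chromosomes lay under the permuted maximum. The bins of AT4G02540 and AT4G04180 are neighbours whose markers differed in 5.17% of lines, so their counts are not independent. Each of these 3 bins rests on 1 marker gene, and with 10 principal components removed the distant count was 235, with 31 targets in the leading bin, that of AT2G14460. All 6 targets named at AT4G02540 lost their call then, as did AT1G14270, AT3G13175, AT3G11560, AT1G29250, EXO and AT4G08240. Each of the 10 components was itself associated with a marker bin (1000 permutations, adjusted p of at most 0.04995). Their removal can therefore also take effects of loci.

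**Figure D4:**
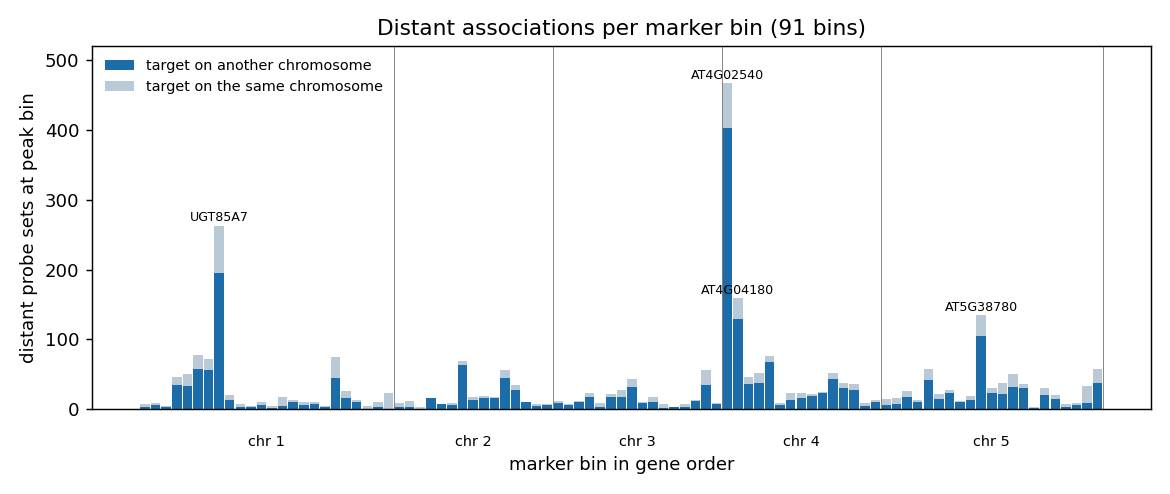
Number of distant probe sets at each of 91 marker bins in gene order along the 5 chromosomes, with targets on another chromosome in dark blue and on the same chromosome in pale blue. The bin of AT4G02540 has 467 targets, followed by the bins of UGT85A7 (263), AT4G04180 (159) and AT5G38780 (135).

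Among the 54 fixed-list genes, 36 were associated with a bin, 11 locally (20.4%, against 21.6% of all nuclear probe sets) and 25 at a distance (46.3%, against 23%). With 10 principal components removed, 9 of the 11 stayed local, 6 of them at the same bin. DFR lost its call then, and AT2G18340 was called at a distance. Of the 25, 0 stayed distant, and AT3G17520 was called locally instead. Each of the 10 components was itself associated with a marker bin, so their removal can also take effects of loci. All 4 fatty acid genes were called: AT5G16230 locally (0.76; 54.9% of variance), and FATB (-0.20; 25.9%), AT5G16240 (-0.15) and FaTA (-0.10) at AT4G02540. The same bin held the seed transcription factor gene EEL (-0.20), the storage protein gene PAP85 (-0.08) and, in the opposite direction, the late embryogenesis abundant gene AT3G17520 (0.66). The photosynthesis genes were 5 of 5 distant, and LHCB4.1 (0.24), PSAE-1 (0.20) and PORB (0.35) shared the bin of AT1G61500. That bin rests on 1 marker gene, with 34.5% of lines in its upper mode where its nearest bimodal gene stood at 44.8%. The pair had 10.6% recombinants, so the score is not shown to follow genotype alone. All 6 glucosinolate genes were called, with AT2G25450 (1.14; 55.9%), AOP1 (0.63; 55.6%) and the transporter gene GTR1 (0.27) local, and AOP3 (0.16), BCAT4 (0.46) and GTR2 (0.34) distant. OLEO3 was local (-0.15; 50.3%), as were the seed coat genes DFR (0.48) and AT3G50990 (-0.67), the bZIP gene BZIP53 (0.26), AUR2 (0.23), AtLEA4-1 (0.38) and AT2G18340 (0.27). Further members with a distant bin were the seed coat genes BAN (0.28) and ARA12 (-0.20), PRL (-0.30), RCA (0.25), LHCB4.2 (0.22), the storage genes AT1G03890 (-0.10) and AT2G28490 (-0.06), the heat shock gene AT1G54050 (0.80), and the late embryogenesis abundant genes LEA (0.19), LEA4-5 (0.32), AT4G21020 (-0.35), AT5G44310 (-0.20) and AT3G22490 (0.08). No endosperm, silique wall or clock gene was called.

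Whether an association differed between Q and R lines was tested for 10803 probe sets, and limma called 0 interactions (589 at unadjusted p under 0.05). The smallest p belonged to AT5G07630, whose change was 0.32 in Q and 0.02 in R lines (adjusted p = 0.213). UGT80B1 changed by -0.30 and -0.04, AT2G22880 by -0.02 and -0.18, and AT4G09850 by 0.01 and 0.18 in Q and R lines. For the locally associated AT2G38180 the changes were 0.94 and 0.73 (adjusted p = 0.321).

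Gene lists varied together across the lines. The score of the photosynthesis genes correlated with that of the cell cycle genes (r = 0.826, rho = 0.803, n = 116; permutation p = 1e-05 for each, the smallest the permutations can give; adjusted p = 4.09e-05 for r and 4.5e-05 for rho). The value was 0.77 in Q and 0.854 in R lines, and 0.796 without the 2 lines farthest from the median. Storage protein scores fell as cell cycle scores rose (r = -0.607, rho = -0.547, -0.503 without 2 lines) and as photosynthesis scores rose (r = -0.594, rho = -0.499, -0.516 without 2 lines). Oil body genes rose with fatty acid genes (r = 0.545, rho = 0.527, 0.513 without 2 lines), and storage genes rose with oil body genes (r = 0.479, rho = 0.483, 0.471 without 2 lines), each at permutation p = 1e-05. Most storage and oil body genes lay near the highest value in the data (14.32) with small SDs. Random lists of like signal had median pairwise correlations of 0.112 and 0.0645, for storage and oil body genes. Permuting lines tests against no correlation and does not allow for what bright probe sets share. Of 45 pairs 29 passed by r, 12 positive and 17 negative, and 25 passed by rho; 27 of the 29 had the same sign in Q and in R lines. With the first principal component removed 11 pairs passed. Photosynthesis with cell cycle genes (r = 0.556, adjusted p = 0.003), oil body with fatty acid genes (r = 0.385, adjusted p = 0.003) and storage with oil body genes (r = 0.327, adjusted p = 0.00337) were among them. Storage genes with photosynthesis genes (r = -0.129, adjusted p = 0.342) and with cell cycle genes (r = -0.169, adjusted p = 0.18) were not.

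**Figure D5:**
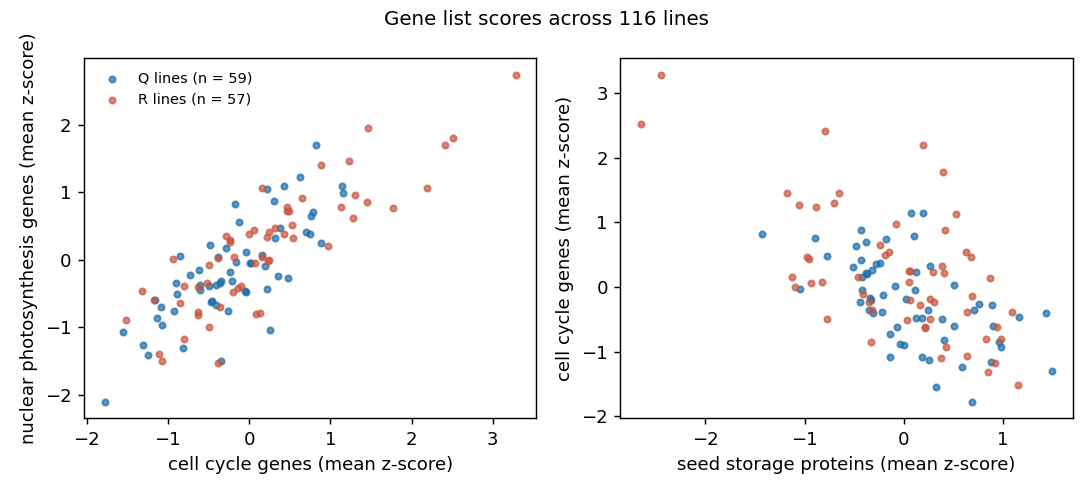
Gene list scores (mean z-score of the members) of Q lines (n = 59) and R lines (n = 57), with 1 point per line. Photosynthesis scores rise with cell cycle scores (r = 0.826, n = 116), and cell cycle scores fall as storage protein scores rise (r = -0.607).

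Members of 7 of the 10 lists tested were more alike across lines than random genes of like signal. Mean pairwise correlations were 0.642 for the cell cycle, 0.613 for photosynthesis, 0.435 for seed coat, 0.331 for plastid, 0.273 for mitochondrial, 0.251 for fatty acid and 0.245 for late embryogenesis abundant genes. The 69 plastid probe sets include 21 called between letters and 30 that rose with the organelle score. Neither the letter nor the score was removed first, so the plastid value does not separate these from other shared variation. The storage (0.366, adjusted p = 0.13), oil body (0.166, adjusted p = 0.376) and glucosinolate genes (-0.0244, adjusted p = 0.716) did not pass against random lists. The first principal component held 12.8% of the variance and 14.3% with dim probe sets left out. It correlated with the scores of storage genes (r = 0.674, rho = 0.605, 0.6 without 2 lines), photosynthesis genes (r = -0.788, rho = -0.769, -0.751 without 2 lines) and cell cycle genes (r = -0.79, rho = -0.734, -0.744 without 2 lines), each at permutation p = 1e-05 over 11 measures. The 3' minus 5' difference correlated with it as well (r = -0.414, rho = -0.387, -0.338 without 2 lines; p = 1e-05 for r and 2e-05 for rho). With this component removed the fatty acid list no longer passed (adjusted p = 0.216).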

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

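The tests with 10 principal components of the values as covariates, with the 3' minus 5' difference in the association scan, of a single nuclear locus for the plastid genes, and of the organelle score were chosen after the results had been seen.

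Nuclear transcripts differed between Q and R lines in 365 probe sets, by a median of 0.136 log2 (median SE 0.0366). Degraded RNA as the whole cause is argued against by the 694 nuclear probe sets called with the 3' minus 5' difference as covariate, and unequal marker shares at the genes' own loci by a ratio of 0.995 between the locally associated shares of called and other nuclear probe sets, although 38.1% of called and 22.8% of other nuclear probe sets were associated at a distance. With 10 principal components of the values as covariates 12 nuclear probe sets were called, 4 of the 365 among them, and the median difference of the 365 shrank to 0.0516 log2 (median SE 0.0292) with 359 of them keeping their sign, so the calls ended because the differences became smaller. Hidden structure of the arrays and an effect of the cytoplasm cannot be told apart here, since the first component itself differed between the letters (p = 0.00257) and the 10 together also took 6 plastid calls, leaving 15 of 21. A nuclear response to the cytoplasm may remain and was not tested apart from them. Unequal marker shares of Q and R lines at distant loci were not tested as a cause either. The first component of probe sets that were not bimodal peaked at the bin of AT5G38780, with 16% of its variance. The upper mode of AT5G38780 held 34 of 59 Q and 21 of 53 R lines (Fisher's exact test, p = 0.062, adjusted p = 0.932).

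Distant associations gathered on the bin of AT4G02540, with 467 targets. Degraded RNA is argued against by the 521 distant targets of the bin with the 3' minus 5' difference as covariate. Over all distant targets, the share of probe set names ending in _s_at or _x_at was 0.582 times that among nuclear probe sets tested. Probe sets annotated to several genes could not count as distant, and the share was not taken for this bin. The ratio therefore does not decide whether probe sets that match several genes play a part. Of 100 permutations of the lines, which keep the correlation between genes, 0 gave a bin with as many targets. With 10 principal components removed the median absolute change of the 467 targets went from 0.174 log2 (median SE 0.0359) to 0.0202 (median SE 0.0254), but the second component itself peaked at this bin, with 18.5% of its variance, so the removal also takes an effect of the locus. A locus there with an effect on many transcripts may be one explanation, and hidden structure that is unevenly spread over its genotypes stays open.

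The plastid genes ndhF, petN and rps14 split the same lines in both letters. A single nuclear locus is argued against by marker bins that accounted for at most 4.37% of the variance of any of them. DNA carried over into the RNA is a candidate explanation: probe sets with _x_at names, which match repeated sequences, rose with the organelle score 131 times as often as other nuclear probe sets (12 of 110 against 11 of 13257), and the 5S ribosomal control rose by 0.89 ± 0.0502 log2 per SD (SE, n = 116). Pseudogenes rose in 16 of 989 nuclear probe sets against 7 of 12378 others (Fisher p = 1.07e-13), but the 25S ribosomal control, also a repeated gene, changed by -0.06 ± 0.0359 (p = 0.0948), and 1 of 18 mitochondrial probe sets rose (median slope 0.03) against 30 of 69 plastid ones (median 0.20), although DNA carry-over or unequal labelling of RNA without poly(A) tails could each raise both, so the cause stays open. None of the 124 bimodal nuclear genes rose or fell by 0.25 log2 or more per SD of the score, and with the score as covariate 661 probe sets were called between letters and 3317 at a distance.

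The letter comparison gave 698 probe sets, and of 100 splits of the lines only 1, the real one, gave as many, with 157 the highest of the others. A count this large is thus unlikely from a random split, although 100 splits can resolve no less than 1 in 100. The count says nothing about single calls. For interactions the real split gave 0, so all 100 splits had to give as many, with 1 the highest of the others, and this count says nothing about chance. Upper modes fell in the same lines in 37.5% of 40 non-overlapping neighbouring pairs (95% Wilson interval 24.2% to 53%), under the share of over 60% set beforehand for modes that arise from probes designed on 1 parent.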

How the results depend on the processing

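Alternatives chosen after the data were seen were 10 principal components of the values as covariates, the 3' minus 5' difference in the association scan, and the organelle score. Of 742 alternative values over 88 results, 688 kept their direction and side of the threshold or stayed within the limit set for a value without a test, 43 fell short of the threshold, 11 moved and 0 reversed. The count between letters, 698, was 4093 with 10 principal components of the residuals as covariates, which are orthogonal to the letter by construction and so lower the residual spread, 1368 with the 3' minus 5' difference and 33 with components of the values; its other alternatives ran from 661 to 971. Among 46 genes named between letters, 30 fell short with components of the values, and accD did when quantile normalised again (difference 0.36 log2 against 0.37, adjusted p = 0.0527). Bimodal probe sets numbered 368 with modes at least 0.5 log2 apart, a looser rule by construction, and genes departing from 1:1 numbered 2 at 5 SD, where fewer genes were tested. With 10 principal components removed, 1854 local and 235 distant associations were called, and 12 of 28 named associations fell short; with the first component removed 11 list pairs passed. For these the cause was not tested beyond the values given with them. The first component held 14.3346% of variance without dim probe sets and 14.3181% without bimodal ones, in each case of fewer probe sets. Background correction cannot be changed from probe set values and was not run. No paired analysis was possible because numbers within the letters follow the order of the samples and the lines differ. Dim probe sets near background limit what small changes can be seen.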

Other observations

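The genes named here as loci of organelle transcripts and as strong distant targets outside the leading bins were chosen after their values were seen, and no test of a cause was made in this part.

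Some transcripts ranged widely between lines without separate modes. GILT (AT4G12960) averaged 8.25 ± 1.98 log2 (SD, n = 116 lines) and ran from 3.99 to 12.33. AT3G58550 averaged 7.24 ± 1.80, AT2G18370 averaged 8.57 ± 1.55 and the acyltransferase gene FACT averaged 6.76 ± 1.53. AT2G23230, AT1G47400, AT1G30700, AT2G15325 and AT2G15220 had SDs between 1.15 and 1.45. The small heat shock protein gene AT1G54050 averaged 6.64 ± 1.23 with a highest value of 10.94, and AT1G53540 averaged 4.39 ± 0.884 with a highest value of 9.75. Among late embryogenesis abundant genes AT3G15670 (SD 0.754) and AT3G17520 (SD 0.709) varied most, and among glucosinolate genes AT2G25450 (SD 0.773) did.

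Organelle transcripts were also associated with nuclear bins. The mitochondrial genes matR (-0.35), cox2 (-0.48), nad4L (-0.31) and a probe set of nad1 (-0.23) peaked at the bin of AT1G48580 on chromosome 1, with 25.6%, 30.7%, 19.9% and 19% of their variance. Other mitochondrial probe sets peaked elsewhere: nad9 (0.34; 21.4%) at AT5G21070, another probe set of nad1 (-0.25; 17.7%) at AT1G12070 and cox1 (-0.30; 13.2%) at scpl42. The plastid genes psbL (-0.27), psbF (-0.27) and psbE (-0.30) peaked at AT5G58980, clpP (0.30; 24.8%) at NRPC2 and psaA (0.49) at UGT85A7. The bin of AT5G58980 rests on 1 marker gene, with 70.4% of lines in its upper mode where its nearest bimodal gene stood at 50.5%. That pair had 18.3% recombinants, so the score is not shown to follow genotype alone. Outside the leading bins, AT5G14680 was associated with the bin of AT1G11270 (0.36; 66.1%), AT3G60920 with that of AT2G14460 (-0.61; 58.6%), and QQS, a gene known for an effect on starch content, with that of AT3G43510 (1.40; 42%). QQS lies on the same chromosome as the bin of AT3G43510, where no bin stands between those of AT3G29280 and AT3G43510. It may therefore count as distant only because of the 3-bin window. Outside the 3 genes that make up the organelle score, the plastid transcripts that rose most with it were ndhG (1.02 ± 0.0306 log2 per SD) and psbT (0.93 ± 0.0423, SE, n = 116); with those 3, 30 of 69 plastid probe sets rose.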
